A study of Homo sapiens with 19 samples.

How the data were processed

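Peripheral blood T cells of 10 controls and 9 patients with immune thrombocytopenia were profiled, with 1 array each. Per the labels' protocols, cells were snap frozen, total RNA was extracted by acid phenol extraction and biotinylated cRNA was made by the standard Affymetrix protocol. The probe sets are those of an Affymetrix human genome-wide 3' expression array, per the probe annotation. Per the submitters' processing notes the values were made with PLIER, which fits a signal per probe set; its version, background handling and normalization between arrays are not given in the sources used here. The deposited values are log2 signals. Their scale and base come from the values themselves: they run from 4.49 to 13.32, and a natural log would put the highest at 609000 on a linear scale, above the 65535 that a 16-bit scanner records. Direction is that of signal, higher for more RNA. Array medians lay between 5.057 and 5.097, and any further centring is unknown.

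The table holds 54675 probe sets, of which 41097 have 1 gene symbol in the platform annotation, 1801 have several and 11777 have none; 62 are Affymetrix control probe sets. No symbol needed updating through its gene identifier. Only probe sets with 1 symbol were used for named genes, and for each of 19740 genes the probe set with the highest mean over all 19 arrays was kept. XIST, TSIX and genes of chromosome Y were left out. Genes whose mean lay under the 40th percentile, 5.14 on the log2 scale, were left out, which left 11844 genes, 1020 of them on probe sets open to cross-hybridisation. Some members of the fixed lists have no probe set with 1 symbol in the annotation used here and were not analysed here.

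Groups were taken from the submitters' labels. Each gene was fitted with limma (version 3.58.1, R 4.3.3) as log2 signal on group, with empirical Bayes moderation and Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05. Differences are ITP minus control. Gene lists were tested with limma's camera at its preset correlation of 0.01, as 1 family of 33 lists with at least 5 tested members each: 8 of markers of other blood cell types and 25 of T cell states or pathways. The estimated correlation and fry were run beside it. All other tests of group differences were two-sided exact permutation tests over all splits of the arrays, 92378 for 19 arrays, 1716 for 13 and 20 for 6, with Benjamini-Hochberg adjustment over the 8 cell types for marker means. Standard errors of list means and marker means are taken over arrays, with separate variances. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

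The tests, lists and the rule for naming genes were fixed before the data were examined. Named genes were, per direction, up to 12 past the threshold with the largest change or, where fewer passed, the genes with the smallest p until 5 were named; up to 4 members per list with the smallest p; and a fixed panel of lineage regulators and cytokines, even below the filter. After the data were seen, 4 members were named for lists that passed and 2 for the others. The panel also held 1 gene that has no probe set with 1 symbol, and it is not reported here.

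Simulated data were made from the residuals of these arrays, dealt to the arrays at random, with 200 of 11844 genes shifted in each of 10 runs. The group fit found 31.3%, 77.2% and 98.8% of genes shifted by 0.5, 1 and 2 on the log2 scale, with a mean of 0.7 false calls per run. With the array set as a block it found 66.3%, 97.9% and 99.5%, with a mean of 5.1 and at most 28 false calls. Camera found a list shifted by 1 in 10 of 10 runs with either correlation. With the preset correlation it also called a mean of 5.9 lists per run that had not been shifted, and with an estimated correlation 0.1. Where control and ITP arrays of the same title number were exchanged, 25 of 100 splits gave any list with an estimated correlation, the real one included. The simulated rate may therefore not hold for the real comparison.

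Control and ITP titles share the numbers 1 to 9. The deviations of same-numbered arrays from their group means correlated by over 0.1 in 9 of 9 pairs (0.14 to 0.85), which met the rule set for pairing. Most same-numbered arrays lay in the same set of 6 or 13 arrays, so the rule could be met without pairing by number. The labels do not say that the numbers are matched, and 3 of 9 ITP arrays correlated best with the control of their own number. With the set of 6 or 13 arrays removed 2 of 9 did, and 7 of 9 pairs were over 0.1 (-0.20 to 0.36). Pairing by number is therefore not shown. The fit with the number as a block, without control replicate 10, was kept as an alternative.

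The other alternatives tried before the data were examined were 16 or 64 added on the linear scale, quantile normalization, median centring, no filter or the 60th percentile, the mean of all probe sets, each probe set by itself, array weights, trended and robust moderation, the exact Wilcoxon test, the 3' over 5' ratio or marker means of monocytes, B cells, NK cells and platelets as covariates, and leaving out each array. Chosen after seeing the data were the array set as a block, the 13 or the 6 arrays alone, the first component score or the neutrophil marker mean as a covariate, and an exact permutation test of list means. A change of sign in a value past no threshold in either setting was counted apart when it moved by at most 2 standard errors, a limit loosened from 1 after the data were seen. The set of 6 arrays was taken at the widest gap in the score on the first principal component.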

Results

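Gene expression was measured in T cells isolated from peripheral blood of patients with immune thrombocytopenia (ITP), an autoimmune disease in which platelets are destroyed, and of controls. The mRNA arrays are one part of a study of microRNAs and immune pathways in T cells in ITP, whose microRNA arrays were not analysed here. There were 19 arrays, 10 of control and 9 of ITP T cells, each read as one person's sample from its title. The deposited values are PLIER signals that lie between 4.49 and 13.32 and are read here as log2 values, since the base is not stated. Array medians were between 5.057 and 5.097, and 69.2% of all values lay below 5.5, so most probe sets were dim. One probe set was kept for each of 19740 genes and 11844 genes were tested. The number of arrays limits the precision of all comparisons: the median standard error of a log2 difference was 0.16.

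The comparison asked which genes and gene groups differ in T cells between ITP and control. No single gene did at the threshold set. As groups, markers of neutrophils and monocytes had higher signals in ITP, with mean log2 differences of 0.69 and 0.41 over the tested markers. Both were larger on 6 arrays that stood apart, described below, at 1.24 and 1.06. Without those arrays they were 0.44 and 0.11, and the monocyte list did not pass the camera test there. The TGF-beta signalling list had lower signals, with a mean log2 difference of -0.16. Of 33 gene lists, 11 passed the camera test with its preset correlation, 6 towards higher and 5 towards lower signals in ITP. Only the neutrophil and TGF-beta lists also passed with a correlation estimated per list. By fry and by an exact permutation test of list means 0 of the 33 lists passed. At least 11 lists passed by camera in 10 of 100 splits of the arrays, the real one included, so chance could not be excluded.

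The first principal component of the tested genes held 74.4% of their variance and set 6 arrays, 3 control and 3 ITP, apart from the other 13, 7 control and 6 ITP. On these 6 arrays the 3' over 5' ratio of the GAPDH and ACTB control probe sets, which rises as RNA degrades, was between 1.82 and 2.68 on the log2 scale, against 0.74 to 1.98 on the other 13. The 3' signal of GAPDH itself was 8.55 to 10.42 on the 6 arrays and 10.54 to 10.89 on the others. Between the groups the ratio did not differ detectably: it was 1.51 ± 0.62 in control (SD, n = 10) and 1.38 ± 0.56 in ITP (SD, n = 9; difference -0.13, two-sided exact permutation p = 0.63). The spread between arrays of one group, taken as each array's median absolute deviation from the mean of the rest of its group, was 0.28 ± 0.11 in control (SD, n = 10) and 0.30 ± 0.11 in ITP (SD, n = 9; two-sided exact permutation p = 0.62). Means in the 6 and in the other 13 arrays are given below for the lists that passed and for lists whose mean differed in sign between these sets, a difference that was not tested.

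**Figure D1:**
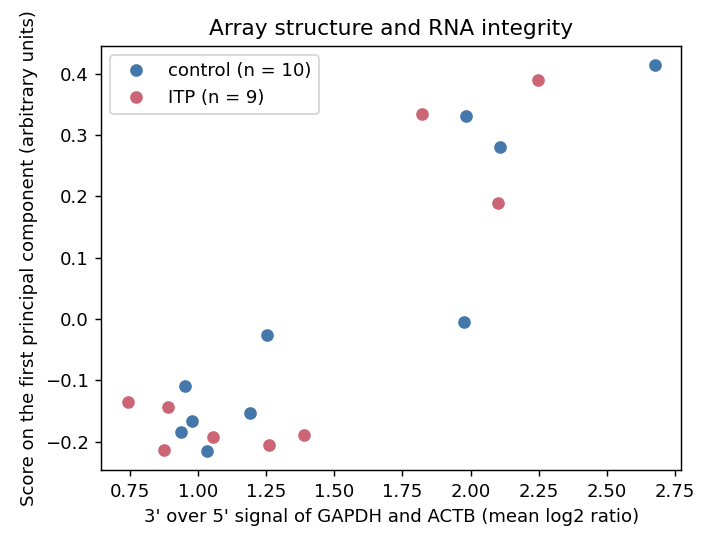
Each point is 1 array, with the mean log2 ratio of 3' over 5' signal of GAPDH and ACTB on the horizontal axis and the score on the first principal component of 11844 genes on the vertical axis, coloured by group. The 6 arrays that stood apart, 3 of each group, have scores from 0.19 to 0.41, and the other 13 lie below 0.

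Single genes with the smallest p are given first, although none passed. S100A8 and S100A9, the subunits of calprotectin in neutrophils and monocytes, had log2 differences of 1.52 (SE 0.44) and 1.38 (SE 0.39), or 2.87-fold and 2.59-fold. These values rest largely on the 6 arrays that stood apart, where the differences were 3.42 and 2.75, against 0.66 and 0.77 in the other 13. S100A9 lay above the control mean on 9 of the ITP arrays and S100A8 on 8. MCEMP1, a membrane protein of mast cells and myeloid cells, had a log2 difference of 0.32 (SE 0.08), CKAP4, a membrane protein of the endoplasmic reticulum, 0.53 (SE 0.16), and ORM1, an acute-phase glycoprotein, 0.41 (SE 0.13). Towards lower signal in ITP, RFFL, an E3 ubiquitin ligase, had a log2 difference of -0.38 (SE 0.08) and RAB8A, a GTPase of vesicle transport, -0.37 (SE 0.09). MED8, a Mediator subunit, had -0.31 (SE 0.07), TAF8, a TFIID subunit read by a probe set open to cross-hybridisation, -0.32 (SE 0.08), and SMKR1 -0.21 (SE 0.06). RFFL, MED8, TAF8 and SMKR1 were below the control mean on 9 of the ITP arrays. In ORM1 and RFFL 1 array stood far from the rest of its group. All 10 of these genes missed the threshold.

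The limma test gave 0 genes higher and 0 lower in ITP at a Benjamini-Hochberg adjusted p under 0.05. The lowest adjusted p of any of the 11844 genes was 0.9999. At an unadjusted p under 0.05 there were 141 genes, 47 higher and 94 lower in ITP, against 592 if p-values were uniform. Random splits of these arrays gave a median of 158 genes and exchanges within the replicate numbers 69. With the array set as a block there were 1052 genes, in the other 13 arrays alone 730 and in the 6 arrays alone 846, with 0 past the threshold in each. The 141 genes therefore do not show fewer differences than chance. The exact Wilcoxon test gave 0 genes past the threshold and 159 at an unadjusted p under 0.05. In data simulated from these arrays the limma group fit found 31.3% of genes shifted by 0.5 on the log2 scale, 77.2% of those shifted by 1 and 98.8% of those shifted by 2, among 11844 genes. With the array set as a block it found 66.3%, 97.9% and 99.5% of them, and on the measured data that fit gave 0 genes past the threshold. The simulation dealt the residuals to the arrays at random, while the real grouping held 3 of the 6 arrays in each group. These shares may therefore not hold for the real comparison.

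Neutrophil markers stood out among the fixed lists. Of 13 tested members, 12 had higher signals in ITP, with a mean log2 difference of 0.69 (SE over arrays 0.23) and a median of 0.57, and the list mean was above the control mean on 9 of the ITP arrays. LTF (lactoferrin) had a log2 difference of 1.48 (SE 0.48), LCN2 (lipocalin 2) 1.35 (SE 0.50), CEACAM8, a surface protein of granulocytes, 1.33 (SE 0.50) and CAMP (cathelicidin) 0.93 (SE 0.34). In the other 13 arrays these differences were 1.05, 0.96, 0.45 and 0.74, and in the 6 arrays 2.52, 2.32, 3.20 and 1.37. LTF, LCN2 and CAMP encode proteins of neutrophil granules. None of the members passed over all genes tested, and 7 passed when adjusted over the list alone. The list rose in ITP by camera (adjusted p = 8.9e-19 with the preset correlation, adjusted p = 0.029 with an estimated correlation). Tested as 1 of 8 other blood cell types, the mean of the markers per array was 5.79 ± 0.53 in control (SD, n = 10) and 6.47 ± 0.48 in ITP (SD, n = 9; two-sided exact permutation p = 0.011, adjusted p = 0.085), which missed the threshold. Its mean log2 difference was 0.44 in the other 13 arrays and 1.24 in the 6 arrays. In the 13 arrays the camera adjusted p was 0.026 with the preset correlation. There the two-sided exact permutation test of the marker means gave p = 0.14 (adjusted p = 0.70), so the difference is not shown outside the 6 arrays. The call was lost with array weights (mean 0.31, adjusted p = 0.086) and with markers of other cell types as covariates (mean 0.22, adjusted p = 0.12). The mean was 0.42 with 64 added on the linear scale and 1.10 with the 60th percentile filter.

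Monocyte markers had higher signals in 15 of 16 tested members, with a mean log2 difference of 0.41 (SE over arrays 0.18) and a median of 0.25. The list mean was above the mean of all 10 control arrays on 9 of the ITP arrays. Within the other 13 arrays the control mean was 6.55 and the ITP arrays ran from 6.47 to 6.99, so not all lay above it. S100A8 and S100A9 were followed by S100A12, a related calcium-binding protein, at 1.05 (SE 0.37) and FCN1 (ficolin 1) at 0.46 (SE 0.18). In the other 13 arrays S100A12 had 0.24 and FCN1 0.33, and in the 6 arrays 2.75 and 0.79. The S100 genes are also abundant in neutrophils. None of the members passed over all genes tested, and 2 did when adjusted over the list alone. The list rose by camera with the preset correlation (adjusted p = 3.7e-10), and the call was lost with an estimated correlation (adjusted p = 0.058). The mean of the markers was 6.43 ± 0.36 in control (SD, n = 10) and 6.85 ± 0.42 in ITP (SD, n = 9; two-sided exact permutation p = 0.034, adjusted p = 0.14). The mean log2 difference was 1.06 in the 6 arrays and 0.11 in the other 13, where the camera adjusted p was 0.59. The call was also lost with array weights (mean 0.03, adjusted p = 0.93) and with the neutrophil marker mean as a covariate (mean 0.03, adjusted p = 0.32).

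**Figure D2:**
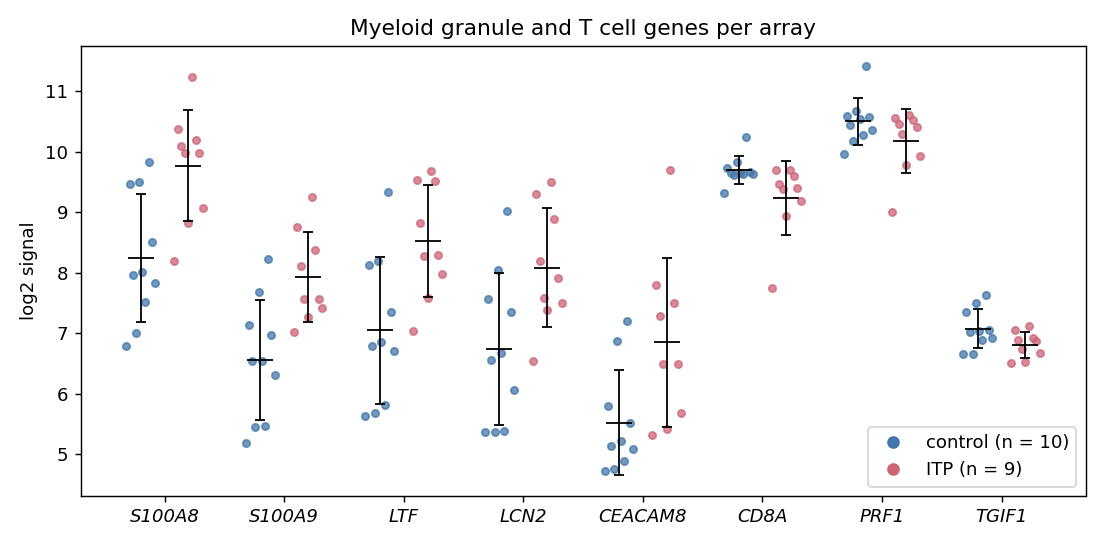
log2 signal per array (points) of calprotectin and neutrophil granule genes, of CEACAM8 and of T cell genes (CD8A, PRF1 and TGIF1), with the mean and SD of each group (bars; control n = 10, ITP n = 9). S100A8 averages 8.25 in control and 9.77 in ITP, and the groups overlap for every gene shown.

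Platelet markers had higher signals in 17 of 17 tested members, with a mean log2 difference of 0.19 (SE over arrays 0.18) and a median of 0.16. PPBP and PF4, chemokines of platelet granules, had log2 differences of 0.51 (SE 0.37) and 0.48 (SE 0.35, a probe set open to cross-hybridisation). CLEC1B, a platelet receptor, had 0.16 (SE 0.08) and ITGA2B, the alpha subunit of the fibrinogen receptor, 0.25 (SE 0.19). The list mean was above the control mean on 5 of the ITP arrays, and without ITP replicate 1 the mean log2 difference was 0.10 (adjusted p = 0.0063), as it was with 64 added (adjusted p = 2.1e-05). The list rose by camera with the preset correlation (adjusted p = 1.8e-06), and the call was lost with an estimated correlation (adjusted p = 0.44). Erythroid markers were higher in 5 of 6 tested members and on 6 of the ITP arrays (mean 0.34, SE over arrays 0.20, median 0.22), and rose by camera with the preset correlation (adjusted p = 0.0021) but not with an estimated correlation (adjusted p = 0.13). HBB, read by a probe set open to cross-hybridisation, had a log2 difference of 1.18 (SE 0.65), HBD 0.41 (SE 0.29), AHSP, a chaperone of alpha-globin, 0.31 (SE 0.21) and HBM 0.08 (SE 0.07). In the other 13 arrays these differences were -0.03, -0.01, 0.08 and 0.05, and in the 6 arrays 3.83, 1.30, 0.80 and 0.15. ITP replicate 8 had the highest signal in each of these genes. Plasma cell markers were higher in 8 of 9 tested members and on 7 of the ITP arrays (mean 0.10, SE over arrays 0.09, median 0.06) and rose by camera with the preset correlation (adjusted p = 0.037), not with an estimated correlation (adjusted p = 0.44). JCHAIN had 0.32 (SE 0.38), FKBP11 0.25 (SE 0.31), SDC1 0.16 (SE 0.12) and IGHG1 0.09 (SE 0.08). The mean log2 differences in the other 13 arrays were 0.18 for platelet, 0.03 for erythroid and 0.01 for plasma cell markers, and none of the 3 lists passed there; in the 6 arrays they were 0.26, 1.01 and 0.28. Without ITP replicate 8 erythroid markers did not pass (mean 0.21, adjusted p = 0.17), and with 64 added their mean was 0.21 (adjusted p = 0.0040). With markers of other cell types as covariates the erythroid mean was -0.08 (adjusted p = 0.54). The plasma cell call was lost without any one of 8 arrays, control replicates 1, 2, 4 and 7 and ITP replicates 4, 7, 8 and 9, with means of 0.06 to 0.10 and adjusted p from 0.056 to 0.38. It was also lost with 16 or 64 added or no filter on dim genes (adjusted p = 0.052, 0.076 and 0.17). With the neutrophil marker mean as a covariate the means were 0.06 for platelet, 0.11 for erythroid and 0.02 for plasma cell markers, and the calls were lost (adjusted p = 0.14, 0.25 and 0.82). By the exact permutation test of the marker means the adjusted p was 0.39 for platelet and plasma cell markers and 0.27 for erythroid markers. In CLEC1B, PF4, ITGA2B, AHSP and SDC1 at least 1 array stood far from the rest of its group.

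B cell and dendritic cell markers did not pass. B cell markers were higher in 6 of 13 tested members (mean 0.00, median -0.02), with SPIB at -0.22 (SE 0.15) and VPREB3 at -0.13 (SE 0.13; camera adjusted p = 0.76, downward although the mean is above 0). Their mean log2 difference was -0.26 in the other 13 arrays, with an adjusted p of 0.021, and 0.54 in the 6 arrays, with an adjusted p of 0.0036; in B cell markers 1 ITP array stood far from the rest. Dendritic cell markers were higher in 4 of 9 tested members (mean and median 0.00, both just below 0 while the test pointed up, and a mean just above 0 under each of the other scalings; adjusted p = 0.68), with IRF8 at -0.27 (SE 0.46) and CD1C, in which 1 array stood far from the rest, at 0.16 (SE 0.28). Their mean was -0.17 in the other 13 arrays and 0.32 in the 6. With markers of other cell types as covariates the dendritic cell list passed downward (mean -0.23, adjusted p = 0.0020). NK cell markers were lower in 10 of 12 tested members and on 6 of the ITP arrays, with a mean log2 difference of -0.14 (SE over arrays 0.13) and a median of -0.09. Among them the receptor genes KLRC3, KLRD1 and KLRF1 had log2 differences of -0.39 (SE 0.14), -0.50 (SE 0.32, a probe set open to cross-hybridisation) and -0.32 (SE 0.34), and NCR1 had -0.06 (SE 0.06). The NK cell list fell by camera with the preset correlation (adjusted p = 0.044), not with an estimated correlation (adjusted p = 0.56). Its mean was -0.18 in the 6 arrays and -0.12 in the other 13, where it missed the threshold (adjusted p = 0.089). The NK cell call was lost without any one of 8 arrays, control replicates 3, 5, 6 and 9 and ITP replicates 4, 5, 8 and 9, with means of -0.15 to -0.07 and adjusted p from 0.071 to 0.38. It was also lost with 16 or 64 added or the 60th percentile filter (adjusted p = 0.054, 0.076 and 0.26), and with the 3' over 5' ratio, the first component score or the neutrophil marker mean as a covariate (means of -0.15 to -0.13, adjusted p = 0.053, 0.12 and 0.14). Without ITP replicate 7 the NK cell mean was -0.21 (adjusted p = 0.0013).

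**Figure D3:**
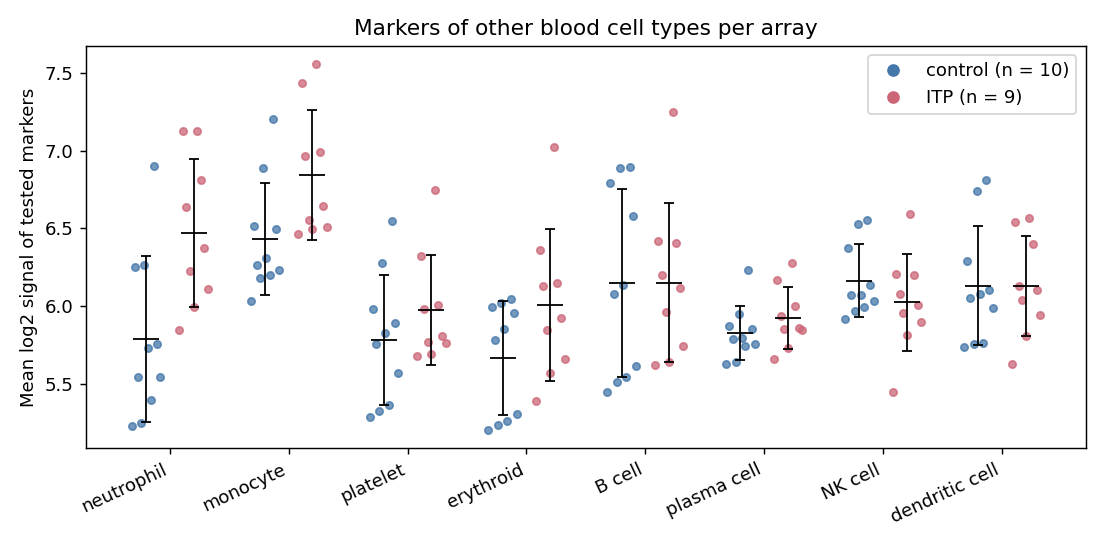
Mean log2 signal of the tested markers of 8 other blood cell types, 1 point per array, with the mean and SD of each group (bars; control n = 10, ITP n = 9). The neutrophil mean is 5.79 in control and 6.47 in ITP, the monocyte mean 6.43 and 6.85, and the B cell means are both 6.15.

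The cytotoxic effector list, genes of killer T cells and NK cells, had lower signals in ITP in 17 of 18 tested members, with a mean log2 difference of -0.27 (SE over arrays 0.30) and a median of -0.30. PRF1 (perforin) had -0.33 (SE 0.20), GZMA (granzyme A) -0.50 (SE 0.32), CX3CR1, the fractalkine receptor, -0.53 (SE 0.35) and NKG7, a cytotoxic granule protein, -0.43 (SE 0.35). The list fell by camera with the preset correlation (adjusted p = 0.00092), not with an estimated correlation (adjusted p = 0.56), and its mean was below the control mean on 4 of the ITP arrays. T cell identity and TCR signalling genes were lower in 19 of 24 tested members, with a mean of -0.13 (SE over arrays 0.15) and a median of -0.15. CD8A, a coreceptor chain of cytotoxic T cells, had -0.46 (SE 0.20), CD3G, a chain of the receptor complex, -0.26 (SE 0.16), LCP2, an adaptor of receptor signalling, -0.20 (SE 0.11) and PLCG1 (phospholipase C gamma 1) -0.17 (SE 0.12). This list fell by camera with the preset correlation (adjusted p = 0.0049), not with an estimated correlation (adjusted p = 0.56), and its mean was below the control mean on 4 of the ITP arrays. Without ITP replicate 8 the means moved to -0.06 for the cytotoxic list and -0.01 for the T cell identity list, and neither passed (adjusted p = 0.38 and 0.43). Without ITP replicate 9 they were -0.19 and -0.08, and neither passed (adjusted p = 0.080 and 0.16). The means were -0.13 and -0.03 in the other 13 arrays, where neither list passed (adjusted p = 0.089 and 0.90), and -0.50 and -0.29 in the 6 arrays. With the neutrophil marker mean as a covariate the T cell identity list did not pass (mean -0.12, adjusted p = 0.083), and the cytotoxic list did. Both calls were lost with markers of other cell types as covariates, with cytotoxic and T cell identity means of 0.07 and 0.04 (adjusted p = 0.44 and 0.82). They were also lost with array weights (means -0.09 and -0.03, adjusted p = 0.16 and 0.46) and with the array set as a block (means -0.24 and -0.12, adjusted p = 0.063 and 0.067). In PRF1, NKG7, CD8A and CD3G 1 array stood far from the rest of its group.

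TGF-beta signalling genes were lower in 13 of 17 tested members, with a mean log2 difference of -0.16 (SE over arrays 0.06) and a median of -0.15, and the list mean was below the control mean on 9 of the ITP arrays. TGIF1, a corepressor of the pathway, had -0.26 (SE 0.13), SKIL, a repressor of SMAD proteins, -0.46 (SE 0.31), ID2, an inhibitor of transcription, -0.43 (SE 0.27) and TGFBR3, a coreceptor, -0.47 (SE 0.37). These members differed between the array sets. In the other 13 arrays they had -0.30, -0.67, -0.18 and -0.06, and in the 6 arrays -0.14, 0.10, -0.90 and -1.49. TGIF1 and SKIL act against the pathway that names the list, and in ID2 1 array stood far from the rest of its group. The list fell by camera (adjusted p = 0.0049 with the preset correlation, adjusted p = 0.046 with an estimated correlation). The mean of this list was -0.10 in the other 13 arrays, where the call was lost (camera adjusted p = 0.089), and -0.30 in the 6 arrays. The call was also lost with array weights (mean -0.09, adjusted p = 0.11), markers of other cell types (mean -0.10, adjusted p = 0.24), the neutrophil marker mean (mean -0.08, adjusted p = 0.23) or the first component score as covariates (mean -0.14, adjusted p = 0.086). With the mean of all probe sets per gene the list mean was -0.08 (adjusted p = 0.030). Glucocorticoid response genes were higher in 13 of 15 tested members and on 7 of the ITP arrays (mean 0.13, SE over arrays 0.07, median 0.07), and rose by camera with the preset correlation (adjusted p = 0.0049), not with an estimated correlation (adjusted p = 0.082). ZBTB16, a transcription factor, had 0.47 (SE 0.29), DDIT4, an inhibitor of mTOR, 0.40 (SE 0.20), TSC22D3, known as GILZ, 0.26 (SE 0.22) and SGK1, a kinase, 0.20 (SE 0.21), and in DDIT4 and TSC22D3 1 array stood far from the rest of its group. SGK1 had -0.04 in the other 13 arrays and 0.68 in the 6, where ITP replicate 8 had the highest signal, 8.21. The glucocorticoid mean was 0.29 in the 6 arrays and 0.05 in the other 13, where it did not pass (adjusted p = 0.49). Its call was lost without ITP replicate 7, 8 or 9 (means of 0.11, 0.13 and 0.13, adjusted p = 0.080, 0.13 and 0.10). With the neutrophil marker mean as a covariate the glucocorticoid mean was 0.06, and with markers of other cell types 0.06, and the call was lost (adjusted p = 0.14 and 0.82). Ribosomal protein genes were lower in 18 of 22 tested members and on 3 of the ITP arrays (mean -0.04, SE over arrays 0.09, median -0.05) and fell by camera with the preset correlation (adjusted p = 0.025), not with an estimated correlation (adjusted p = 0.59). RPL27 had -0.15 (SE 0.10), RPS12 -0.09 (SE 0.08, a probe set open to cross-hybridisation), RPS23 -0.08 (SE 0.08) and RPL30 -0.08 (SE 0.05). The mean of that list was -0.06 in the other 13 arrays (adjusted p = 0.024) and 0.02 in the 6 arrays (adjusted p = 0.38). The ribosomal call was lost without any one of 8 arrays, control replicates 1, 2, 4, 5 and 7 and ITP replicates 4, 8 and 9, with means from -0.03 to 0.02, the last without ITP replicate 8, and adjusted p from 0.065 to 0.58. It was also lost with quantile normalization, median centring, the 60th percentile filter or the mean of all probe sets (adjusted p = 0.073, 0.076, 0.15 and 0.086). The ribosomal mean was -0.08 without control replicate 8 and -0.07 without ITP replicate 5.

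**Figure D4:**
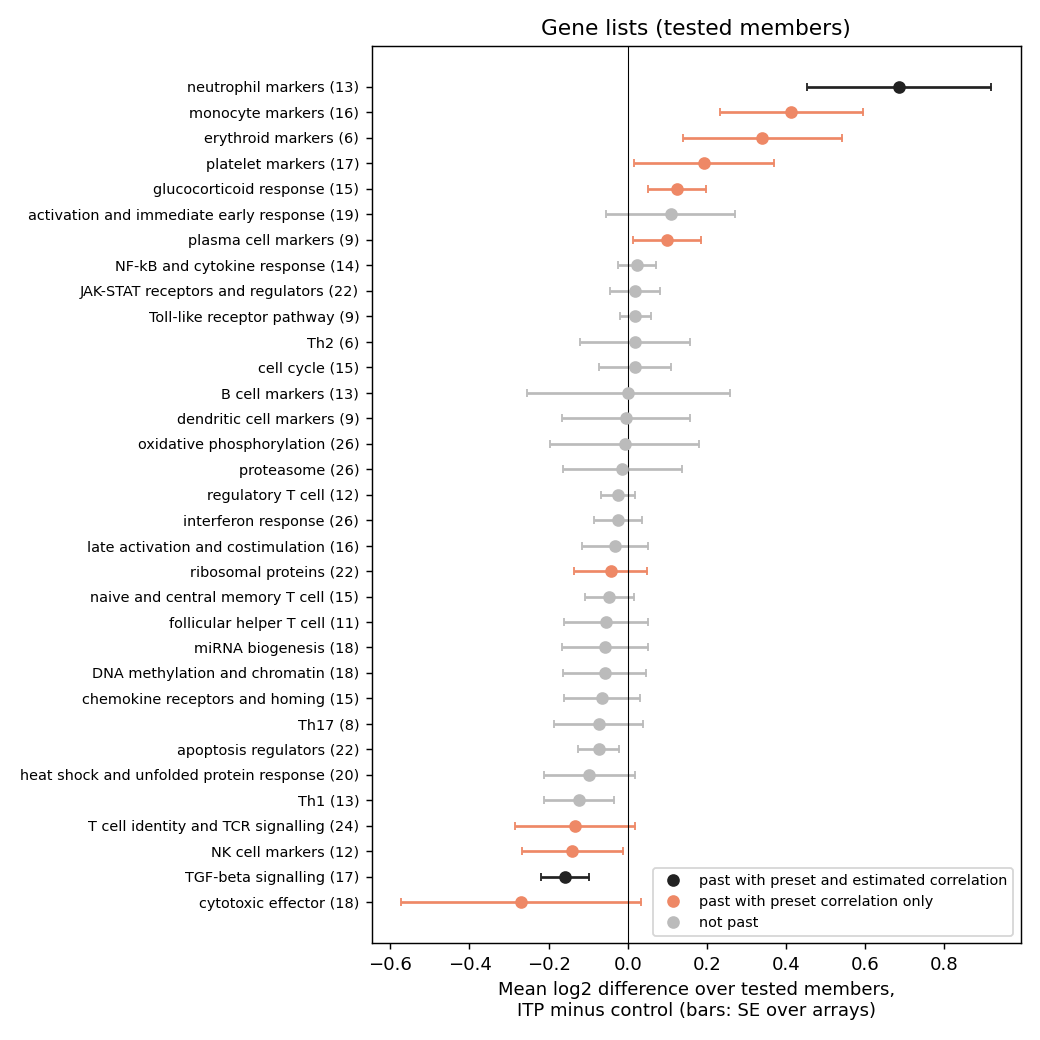
Mean log2 difference over the tested members of each of the 33 lists, ITP minus control (points), with the standard error over arrays (bars); the number of tested members is in brackets and the colour gives the camera call. The neutrophil list lies at 0.69 and the TGF-beta list at -0.16, and these are the lists that passed with both correlations.

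Helper T cell lists did not pass by camera with the preset correlation in the fit to all 19 arrays. Th1 genes were lower in 9 of 13 tested members (mean -0.12, median -0.14, adjusted p = 0.084), with EOMES, a regulator of effector cells, at -0.50 (SE 0.24), TBX21, the Th1 regulator, at -0.30 (SE 0.23) and IFNG (interferon gamma) at -0.25 (SE 0.15). With the replicate number as a block, which leaves out control replicate 10, the Th1 list passed (mean -0.14, adjusted p = 0.016), as it did without that array and no block (mean -0.14, adjusted p = 0.027). It passed too without any one of control replicates 2 and 8 and ITP replicates 6 and 7 (means of -0.16 to -0.14, adjusted p from 0.0191 to 0.0496). The Th1 list also passed with median centring, no filter or the neutrophil covariate (adjusted p = 0.043, 0.028 and 0.014). Without ITP replicate 8 the Th1 mean was -0.07 (adjusted p = 0.30), and with markers of other cell types as covariates -0.03 (adjusted p = 0.44). Th2 genes were higher in 4 of 6 tested members (mean and median 0.02, adjusted p = 0.45), with NFIL3 at 0.07 (SE 0.13), IL1RL1 at 0.02 (SE 0.04) and GATA3, the Th2 regulator, at -0.02 (SE 0.18). Th17 genes were lower in 5 of 8 (mean -0.07, median -0.03, adjusted p = 0.68), with KLRB1 at -0.40 (SE 0.34) and AHR at -0.14 (SE 0.18). Regulatory T cell genes were lower in 9 of 12 (mean -0.02, median -0.03, adjusted p = 0.65, and a mean of 0.00 just above 0 with median centring), with IL2RA at -0.08 (SE 0.07), IKZF4 at -0.05 (SE 0.08), FOXP3, the regulator of these cells, at -0.01 (SE 0.04) and TGFB1, the cytokine TGF-beta 1, at 0.12 (SE 0.41). The mean of the regulatory list was -0.04 in the other 13 arrays and 0.01 in the 6. Follicular helper genes were lower in 7 of 11 (mean -0.05, median -0.07, adjusted p = 0.45), with TOX at -0.38 (SE 0.25), ASCL2 at -0.25 (SE 0.16) and BCL6, the regulator of the lineage, at 0.23 (SE 0.19). BCL6 had 0.01 in the other 13 arrays and 0.63 in the 6, where ITP replicate 8 had the highest signal, 7.89. Naive and central memory genes were lower in 10 of 15 (mean -0.05, median -0.04, adjusted p = 0.33), with S1PR1, a receptor for exit from lymph nodes, at -0.30 (SE 0.12) and SATB1 at -0.21 (SE 0.16). The cytokine genes CXCL13, IL21, IL2 and TSLP lay below the filter on dim genes, with mean signals of 4.78 to 4.91 in both groups. Without the filter their log2 differences were 0.03 (SE 0.03), 0.04 (SE 0.01), 0.01 (SE 0.02) and 0.02 (SE 0.02), with adjusted p = 0.99999 for each. In TBX21, NFIL3 and CXCL13 at least 1 array stood far from the rest of its group.

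Activation, signalling and survival lists did not pass in the fit to all 19 arrays. Activation and immediate early genes were higher in 12 of 19 tested members (mean 0.11, median 0.06, adjusted p = 0.060), with EGR1 at 0.53 (SE 0.43) and NFKBIA at 0.44 (SE 0.34). Activation genes passed without any one of control replicates 1, 6, 7 and 9 and ITP replicates 1, 4 and 9 (means of 0.09 to 0.20, adjusted p from 0.0055 to 0.047), with quantile normalization (adjusted p = 0.0497), with the 60th percentile filter (adjusted p = 0.014) and in the 6 arrays alone (adjusted p = 0.017). Their mean was 0.02 without control replicate 8, 0.05 without control replicate 10 and 0.06 without ITP replicate 3, and did not pass there (adjusted p = 0.46, 0.36 and 0.34). With the neutrophil marker mean as a covariate it was -0.10 (adjusted p = 0.14), with the 3' over 5' ratio 0.05 (adjusted p = 0.17), with the first component score 0.06 (adjusted p = 0.14) and with markers of other cell types 0.04 (adjusted p = 0.96). Late activation and costimulation genes were lower in 9 of 16 (mean -0.03, median -0.01, adjusted p = 0.65), with SLAMF7 at -0.45 (SE 0.30) and CD44 at -0.16 (SE 0.10). Interferon response genes were lower in 17 of 26 (mean -0.02, median -0.04, adjusted p = 0.65, and a mean of 0.00 just above 0 with median centring), with the antiviral genes OAS2 at -0.36 (SE 0.15) and MX2 at -0.16 (SE 0.10). JAK-STAT receptors and regulators were higher in 11 and lower in 11 of 22 (mean 0.02, median 0.01, adjusted p = 0.44), with SOCS1, an inhibitor of the pathway, at 0.41 (SE 0.22) and IFNGR2 at 0.28 (SE 0.12). NF-kB and cytokine response genes were higher in 9 of 14 (mean 0.02, median 0.03, adjusted p = 0.49), with TNFAIP8 at -0.23 (SE 0.33, a probe set open to cross-hybridisation) and RELA at -0.12 (SE 0.18). Toll-like receptor pathway genes were higher in 4 of 9 (mean 0.02, median -0.01, test upward with adjusted p = 0.68), with IRAK3 at 0.30 (SE 0.18) and TIRAP at -0.07 (SE 0.08, open to cross-hybridisation). Chemokine receptor and homing genes were lower in 11 of 15 (mean -0.07, median -0.10, adjusted p = 0.45), with CCR1 at -0.15 (SE 0.12) and CXCR6 at -0.12 (SE 0.14). Apoptosis regulators were lower in 15 of 22 (mean -0.07, median -0.09, adjusted p = 0.14), with CASP10 at -0.16 (SE 0.07) and DIABLO at -0.16 (SE 0.10). The apoptosis list passed with no filter on dim genes (adjusted p = 0.019). Means in the other 13 and in the 6 arrays were -0.10 and 0.11 for late activation, -0.04 and 0.04 for interferon response, -0.02 and 0.10 for NF-kB, and -0.02 and 0.10 for Toll-like receptor genes. In CD44, MX2, IFNGR2, IRAK3 and DIABLO 1 array stood far from the rest of its group.

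Lists of housekeeping and regulatory machinery, other than ribosomal proteins, did not pass in the fit to all 19 arrays. MiRNA biogenesis genes were lower in 13 of 18 tested members (mean -0.06, median -0.05, adjusted p = 0.44), with AGO1 at -0.21 (SE 0.13), ADAR at -0.18 (SE 0.19) and DICER1, the enzyme that cuts precursor microRNAs, at -0.03 (SE 0.35). DNA methylation and chromatin genes were lower in 12 of 18 (mean -0.06, median -0.07, adjusted p = 0.44), with TET3 at -0.29 (SE 0.26) and DNMT3B at -0.06 (SE 0.05). Heat shock and unfolded protein response genes were lower in 15 of 20 (mean -0.10, median -0.12, adjusted p = 0.072), with HSPA5 at -0.25 (SE 0.21) and HSPE1 at -0.22 (SE 0.13). The heat shock list passed in the other 13 arrays, with a mean of -0.13 and an adjusted p of 0.021, and without any one of control replicates 3, 4 and 5 and ITP replicates 2 and 7 (means of -0.15 to -0.11, adjusted p from 0.011 to 0.046). It also passed with median centring, no filter or the mean of all probe sets (adjusted p = 0.039, 0.011 and 0.038). The heat shock mean was -0.06 without any one of control replicate 9 and ITP replicates 1, 5 and 6 (adjusted p from 0.30 to 0.40). With the neutrophil marker mean as a covariate it was 0.01 (adjusted p = 0.94), and with the 3' over 5' ratio -0.06 (adjusted p = 0.60). Cell cycle genes were higher in 9 of 15 (mean 0.02, median 0.03, adjusted p = 0.45; 0.05 without control replicate 8, where it passed with adjusted p = 0.0496), with BIRC5 at 0.30 (SE 0.23) and PCNA at -0.13 (SE 0.12). Without ITP replicate 8 the cell cycle mean was -0.05 (adjusted p = 0.43). Oxidative phosphorylation genes were lower in 15 of 26 (mean -0.01, median -0.03, adjusted p = 0.68, and a mean of 0.02 with median centring), with UQCRB at -0.18 (SE 0.15) and NDUFS1 at -0.11 (SE 0.11). Proteasome genes were lower in 14 of 26 (mean and median -0.01, test upward with adjusted p = 0.96, and a mean of 0.01 with median centring), with PSMA4 at -0.18 (SE 0.20) and PSMA2 at -0.16 (SE 0.20). Means in the other 13 and in the 6 arrays were -0.04 and 0.11 for cell cycle and -0.03 and 0.07 for proteasome genes, the last past the threshold in the 6 (adjusted p = 0.048). With markers of other cell types as covariates the cell cycle list passed downward (mean -0.09, adjusted p = 0.035). In DNMT3B, HSPE1 and BIRC5 1 array stood far from the rest of its group.

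Of the 521 distinct genes tested on the 33 lists, none passed over all genes tested. Adjusted over the list alone, members passed in the neutrophil and monocyte lists only. By fry, which tests each list by itself, 0 of 33 lists passed; 2, the neutrophil and TGF-beta lists, had an unadjusted p under 0.05, with adjusted p = 0.22 for both, and camera gave the 11 lists above. By an exact permutation test of the list means, chosen after seeing the data, the adjusted p was 0.27 for both lists. Without ITP replicate 8 the number of lists past the camera threshold was 4 and without ITP replicate 9 it was 6, against 11 with all 19 arrays. Without the 6 arrays that stood apart it was 4, of which 2, the neutrophil and ribosomal lists, were among the 11. With the array set as a block it was also 4, the neutrophil, monocyte, platelet and TGF-beta lists. With array weights no list passed by camera, and with markers of other cell types as covariates 2 did, the cell cycle and dendritic cell lists, neither of them among the 11. The monocyte, platelet and NK cell lists, which are among the 11, served as covariates there. That removes their mean group difference, so their loss was fixed in advance.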

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

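The tests of the neutrophil markers, of the arrays that stood apart and of the TGF-beta list, the last without those arrays and with the neutrophil covariate, were chosen only after the results were seen, as was the count with an estimated correlation within numbers; the bounds for the covariate and for the other splits were set before their values were seen.

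Single arrays far from the rest of their group were looked for in 236 groups of values, the marker means, RNA quality, spread and 106 named genes in each group, by the gap to the nearest array over the range of the group. In 30 groups the gap exceeded the 95% limit, where chance gives about 1 in 20 groups, or 12; 22 of the 30 arrays were among the 6 that stood apart. In ITP 1 array lay above the others in B cell markers (gap 0.51 of the range), BIRC5 (0.691), CD1C (0.52), AHSP (0.78), MX2 (0.54), CD44 (0.534), SDC1 (0.787), PF4 (0.493), ITGA2B (0.61), NFIL3 (0.781) and CXCL13 (0.635). In ITP 1 array lay below the others in RFFL (0.56), NKG7 (0.735), TSC22D3 (0.575), HSPE1 (0.659), CD8A (0.611), CD3G (0.537) and TBX21 (0.62). Among controls 1 array lay above the others in ORM1 (0.623), DIABLO (0.501), PRF1 (0.513), DNMT3B (0.636), CLEC1B (0.493), ITGA2B (0.471), IRAK3 (0.592), CXCL13 (0.622) and TBX21 (0.486), and below them in DDIT4 (0.47), IFNGR2 (0.496) and ID2 (0.643).

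Neutrophil markers were higher in ITP by a mean of 0.69 on the log2 scale. Monocyte RNA alone stays open: over all tested members the neutrophil list differed by 0.27 more than the monocyte list (SE 0.16, two-sided exact permutation p = 0.11), which decides nothing, since S100A8, S100A9 and S100A12 of the monocyte list are also abundant in neutrophils. A candidate explanation is neutrophil RNA in the T cell preparations, which stays undecided. After group and array set were removed the 13 markers, none of which is on another list, rose and fell together. Their mean pairwise correlation was 0.49, against 0.097 at the 95th percentile of 1000 random lists matched on mean signal. Such a correlation does not bear on the group difference. By camera's estimate members of the B cell list, with a mean difference of 0.00, correlated by 0.55, and those of the neutrophil list by 0.41. S100A8 and S100A9 had log2 differences of 1.52 and 1.38. The neutrophil receptor genes FCGR3B and CXCR2, named after their values were seen, had 0.05 (SE 0.19) and -0.04 (SE 0.14), and no sort or gate is given in the labels. The 6 arrays stay open as part of it, because the difference in the other 13 was 0.44 (SE 0.28, two-sided exact permutation p = 0.14), neither near 0 nor past 2 standard errors. Whether more neutrophil RNA would come from the isolation or from the blood of the patients was not tested, and a difference within T cells stays open.

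The 6 arrays stood apart on the first component. A difference in hybridisation stays open. By the rule set it would be argued against, since 1 of the 6 had bacterial hybridisation spikes outside the range of the other 13. That range rests at its top on ITP replicate 5 at 9.24, with ITP replicate 2 next at 8.54, while ITP replicate 8, of the 6, had 8.71. As normalization between arrays is also unknown, this test does not decide. These spikes do not measure labelling, which was not tested. Loss of RNA integrity stays open: 5 of the 6 had a 3' over 5' ratio above all of the other 13, but within the 13 arrays the score and the ratio had r = 0.56 (permutation p = 0.056, adjusted p = 0.11) and rho = 0.099 (permutation p = 0.75, adjusted p = 0.75), and without the 2 arrays farthest from the median ratio r = 0.19, so the relation rests on those arrays. Within the 6 arrays r = 0.49 (exact permutation p = 0.32) and rho = 0.49 (exact permutation p = 0.36; without the 2 farthest r = 0.34; adjusted over the 2 relations computed p = 0.32 and 0.71). The mean signal of the T cell identity list was 7.260 to 8.314 on the 6 arrays and 8.315 to 8.590 on the other 13, so it was lower on each of the 6. What lies behind this was not tested. The set held 3 arrays of each group, and no biological explanation was tested.

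TGF-beta signalling genes were lower in ITP by a mean of 0.16 on the log2 scale, a log2 difference of -0.16 (SE 0.06). The 6 arrays as the whole cause stay open. In the other 13 the difference was -0.10 (SE 0.04, two-sided exact permutation p = 0.020, unadjusted), but the camera call was lost there (adjusted p = 0.089). The list was singled out by its result over all 19 arrays, which include these 13, so that p does not decide. Over all 19 arrays the exact permutation test gave an adjusted p of 0.27. RNA of neutrophils stays open: with the neutrophil marker mean as a covariate the difference was -0.081 (SE 0.072), within 2 standard errors of 0, as the difference shrank and its error grew, and it kept over 0.5 of its size, so this test does not decide. A difference in the T cells of the patients stays among the open explanations and may be followed up, untested here.

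For the count of genes the splits decide nothing, since 0 genes in the real grouping are matched by any split, here 100 of 100, the real one included. The highest of the others gave 6241 genes; that split put all 6 arrays that stood apart in one group, which points to the structure of the arrays, and with the array set as a block the real grouping gave 0. Chance could not be excluded for the counts of lists. As many as the real 11 lists came from 10 of 100 splits, with 14 as the highest of the others, and with an estimated correlation as many as the real 2 lists came from 6 of 100, with 4 as the highest. Many of these random splits did not keep the 6 arrays evenly divided, as the real grouping does. The shares may therefore not hold for splits that do. Where arrays were exchanged within the numbers 1 to 9, which parts as many pairs as the real grouping, 17 of 100 splits gave at least 11 lists, with 15 as the highest of the others. With an estimated correlation 14 of 100 of these exchanges gave at least 2 lists, with 7 as the highest of the others. The exchanges gave 0 genes, and the random splits differ in that they can put both arrays of a number in one group.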

How the results depend on the processing

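The counts of genes higher and lower in ITP were 0 under each alternative, from 0 to 0 when each array was left out. At most 1052 genes had an unadjusted p under 0.05 (array set as a block, chosen after seeing the data, as were the other settings on the 6 arrays, the neutrophil covariate and the list permutation), and the lowest adjusted p there was 0.48. The 11 lists past the camera threshold became 2 with an estimated correlation, 0 with fry, 0 with array weights, 2 with marker means of other cell types as covariates, 4 with the array set as a block, 4 without the 6 arrays, 3 with the neutrophil covariate and 0 with the exact permutation of list means. The cause was not tested, except that fewer arrays enter without the 6. Leaving out 1 array gave 4 to 13 lists, 4 without ITP replicate 8 and 6 without ITP replicate 9. With the replicate number as a block, the pairing by number, 12 lists passed, all 11 and Th1; this fit leaves out control replicate 10, and without that array and no block the same 12 lists passed, so the change is not shown to come from the pairing. Over 1279 list values 123 lost and 35 gained a call. Another 95 changed sign without a call in either setting and by at most 2 standard errors, as did 83 of 3995 values of named genes. Larger or called changes of sign came with marker covariates for the cytotoxic (0.0707), erythroid (-0.0833), T cell identity (0.0380), ribosomal (0.0270), plasma cell (-0.0152) and cell cycle (-0.0939) lists and for DIABLO (0.0558), BIRC5 (-0.21), HBB (-0.24) and HBD (-0.19); with the neutrophil covariate for CAMP (-0.0561) and LCN2 (-0.0372), which are part of that covariate. They also came with array weights for plasma cell markers (-0.00829); without the 6 arrays for B cell markers (-0.26); in the 6 arrays alone for ribosomal (0.0154) and proteasome genes (0.0680); and without ITP replicate 8 for ribosomal genes (leave-one-out range -0.0839 to 0.0201). For these too the cause was not tested. Lists used as covariates got no value in that setting. A list's own mean as a covariate removes its mean group difference, so part of the falls to 2 and to 3 lists was fixed in advance. RNA quality, the spread between arrays and the other cell type markers stayed on their side of the threshold in 4, 2 and 24 alternative values; 9 more, in the 6 arrays alone, could not pass it, since the smallest p there is 0.1. Low signal over background limits dim genes such as the cytokine genes named, as 69.2% of values lay below 5.5.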

Other observations

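Genes outside the lists moved with the neutrophil markers in direction, chosen here after their values were seen: HP (haptoglobin) had a log2 difference of 0.74 (SE 0.23, adjusted p = 0.9999 by limma) and S100P, a calcium-binding protein of granulocytes, 1.02 (SE 0.33, adjusted p = 0.9999), both above the control mean on 9 of the 9 ITP arrays. In the other 13 arrays their log2 differences were 0.43 and 0.59. Neither passed the threshold.

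Probe sets without a single gene symbol numbered 13581, of which 4505 lay above the filter. By limma 0 of them passed an adjusted p under 0.05, and 44 had an unadjusted p under 0.05, against 225 if p-values were uniform.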
